A study of Mus musculus with 10 samples.

How the data were processed

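RNA of sorted mouse bone marrow cells was measured on 10 Affymetrix arrays, 1 per sample, in 3 groups: GFP vector (3), AML1/ETO (3) and AML1/ETO with W692A (4). Per the labels, cells of C57BL/6 mice were transduced with MigR1 retrovirus, sorted 48 hours after the second transduction as lineage-negative, Sca1-positive, cKit-positive and GFP-positive, and 50 ng of RNA from 25000 cells was amplified in more than one round and labelled with biotin. The groups were taken from the sample labels, which describe independent transductions; whether each came from other mice is not given in the sources used here. A gate on lineage-negative cells is meant to leave out mature blood cells. With GFP some granule genes were still bright, such as Chil3 (9.35 to 9.81) and Epx (7.5 to 8.2). Others were dim, such as Mmp8 (0.81 to 1.32).

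The deposited values are log2 intensities, 1 per probe set and array, from RMA per the submitters' processing notes, with no version given. The base of the logarithm was not stated. The values run from -0.18 to 12.77, and the highest would be 350219 as a natural logarithm, above the 65535 that a 16-bit scanner can record, against 6967 in base 2, so base 2 was used. RMA sets the probe intensities of the arrays to 1 distribution before they are summarised per probe set, which hides differences in total RNA between groups. For arrays, their number limits the precision.

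Of 45101 probe sets, 64 were controls and 9160 others had no listed gene. Of the 35890 listed, 34958 had 1 gene symbol and 932 had several, which were not used. The listed ones include 13 controls, which were kept out of the genes tested. Symbols were updated by gene identifier to the annotation of assembly GRCm38.p6 for 34754 probe sets, and 204 kept the platform's name. Each gene was represented by the probe set with the highest mean over all arrays, which gave 18193 genes, 9010 of them with several probe sets. Other probe sets of a named gene did not always pass. Between AML1/ETO and GFP the 1 other probe set of Inf2 did not, and 3 of 7 others of Cp did. With the mean of a gene's probe sets 13 calls of named genes were lost. For Runx1 the probe sets disagreed in 1 comparison, as reported.

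Differences between groups were tested with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes in 1 fit of all 3 groups, with 7 residual and 7.53 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The 25 gene lists were tested with camera at a preset inter-gene correlation of 0.01, and adjusted over 75 tests together. Of 26 calls, 7 held with an estimated correlation. Effects of both constructs were compared by a slope over all genes with the noise of the estimates and of the shared controls removed, beside 20 draws of simulated unchanged groups.

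The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The lists were stem and multipotent progenitor; neutrophil and granule; monocyte, macrophage and dendritic cell; erythroid; megakaryocyte and platelet; B lymphoid; T and NK lymphoid; mast cell, basophil and eosinophil; stromal and endothelial; S phase and DNA replication; G2 and M phase; p53 targets and CDK inhibitors; DNA repair; reported AML1/ETO and RUNX1 targets; blood transcription factors; ETO family, corepressors and partners; interferon response; Notch; Wnt; immediate early; heat shock and unfolded protein; apoptosis; cytokine receptors and integrins; cytosolic ribosomal proteins; and oxidative phosphorylation. Named genes were, per comparison, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and up to 2 members of each list that rose and 2 that fell. Genes with provisional names were skipped in naming. Runx1, Runx1t1 and Kit were always given; Ly6a and some other list members were not analysed here. Psmb8 was named after its values were seen.

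Chosen after seeing the data were the background bound of 2.04 and fits with the spike-in level or the Gapdh 3′ minus 5′ difference of each array as a covariate, or restricted to the 8820 genes with a group mean above the bound. The bound is the brightest value on any array of the bacterial dap, lys, phe, thr and trpn control probe sets. The brighter labelled spike-in controls (bioB, bioC, bioD and cre) were not used for it. A fold against a dimmer group with any array below the bound was given as a lower limit, computed with those values set to the bound. Alternatives set in advance were a filter on the dimmest 40% of genes, every probe set or the mean of a gene's probe sets, further quantile normalization, median subtraction, another variance prior, fits of 2 groups, array weights, the replicate number as a block, a 1.5-fold minimum, fry in place of camera, and leaving out each array in turn. The fit was tested on simulated data of 18193 genes with 100 changed genes per size, where it recovered 93.0% of 2-fold and 45.0% of 1.5-fold changes for W692A against GFP and 89.0% and 53.0% for W692A against AML1/ETO. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.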

Results

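Expression was measured on 10 mouse arrays. The bone marrow cells carried the surface markers of stem and progenitor cells, lineage negative, Sca1 positive and cKit positive. They had been transduced with a retrovirus and sorted for its green fluorescent marker. The virus encoded the marker alone (GFP, 3 arrays), the leukaemia fusion protein AML1/ETO (3 arrays), or AML1/ETO with the W692A substitution (4 arrays). The substitution lies in the MYND domain, a part of ETO that binds corepressors. The samples came from independent transductions, and 25000 cells were sorted 48 hours after the second transduction. The number of arrays limits the precision. Over genes with a mean above the background bound, arrays of the same group correlated at 0.982 to 0.992 and arrays of different groups at 0.887 to 0.962, and no array was a copy of another. Where a gene lay below the background bound of 2.04 on any array of the dimmer group, its fold is a lower limit, computed with those values set to the bound, and is written as at least that size. The number of arrays above the bound is given where it was neither all nor none. Genes are called the largest rises and falls by log2 differences that include values below the bound, so their order is not that of the printed folds. Counts adjusted over the list alone are given where they differ from those over all genes, and where a list's counts are said to be the same.

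Control signals were compared between groups. The labelled spike-in controls averaged 8.82 ± 0.378 (log2, SD, n = 3) with GFP, 8.27 ± 0.312 (n = 3) with AML1/ETO and 8.67 ± 0.317 (n = 4) with W692A. The difference between the 3′ and 5′ Gapdh control probe sets, a measure of RNA integrity and amplification length, was 4.93 ± 0.0889 (n = 3) with GFP, 4.38 ± 0.573 (n = 3) with AML1/ETO and 4.01 ± 0.168 (n = 4) with W692A. AML1/ETO replicate 3 had a difference of 5.04, against 4.08 and 4.01 on the other AML1/ETO arrays. Signal of the 18S ribosomal RNA control probe sets, another sign of RNA quality, averaged 7.95 ± 0.196 (n = 3) with GFP, 8.40 ± 0.236 (n = 3) with AML1/ETO and 8.76 ± 0.181 (n = 4) with W692A, and every array of both constructs exceeded every GFP array. The 3′ minus 5′ difference of the actin control was 5.78 ± 0.201 (n = 3) with GFP, 5.41 ± 0.285 (n = 3) with AML1/ETO and 5.24 ± 0.182 (n = 4) with W692A, and every W692A array lay below every GFP array.

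The first comparison asks what AML1/ETO changed against the empty vector. By log2 difference, the largest rises were in Hbb-y, an embryonic beta-like globin, which was at least 88.2-fold higher with AML1/ETO, in Gimap4, a GTPase of immune cells (at least 68.6-fold), in the neutrophil-attracting chemokine genes Cxcl3 (at least 62.0-fold) and Cxcl2 (75.4-fold), and in Fbp1, which encodes the gluconeogenic enzyme fructose bisphosphatase (at least 56.4-fold). Further rises were those of Rhoj (69.9-fold), Vegfc, a lymphatic growth factor (62.2-fold), Fst, which encodes the activin antagonist follistatin (at least 31.8-fold), Epas1, a hypoxia-inducible transcription factor (at least 23.7-fold), and Nts, the neurotensin precursor (at least 22.8-fold). The largest falls were in Hemgn, an erythroid nuclear protein (at least 40.8-fold lower), Bex6 (at least 19.3-fold) and Ffar2, a receptor for short-chain fatty acids (14.7-fold). Next came Aqp1, a water channel of red cells (at least 5.93-fold), Tesc (at least 10.4-fold) and Epx, the eosinophil peroxidase (13.6-fold). They were followed by Azin2 (12.1-fold), Inf2, a formin (at least 7.87-fold), Cp, the copper protein ceruloplasmin (at least 10.3-fold), and Sh2d5 (at least 10.7-fold). On the log2 scale Hbb-y differed by 8.02 ± 0.217 (SE, 3 arrays against 3, limma adjusted p = 3.93e-12) and Hemgn by -5.50 ± 0.202 (limma adjusted p = 6.79e-11). The AML1/ETO signal exceeded the background bound on 1 of 3 arrays for Hemgn and Tesc and on 2 of 3 for Cp and Sh2d5.

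With AML1/ETO, 5207 of 18193 genes passed the limma threshold, 2339 higher and 2868 lower. Of these, 3782 differed by at least 1.5-fold and 591 had both group means at or below the background bound. In simulated data with the same arrays per group the fit recovered 82.0% of genes changed by 2-fold and 35.0% of those changed by 1.5-fold. Only 100 genes of each size were changed there, far fewer than were called here. Those shares therefore do not tell how many changes were missed among the real genes.

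Interferon response genes rose together with AML1/ETO: 26 of 27 measured members rose, 0 fell and 1, Psmb8, did not pass, with the same counts adjusted over the list alone (camera adjusted p = 6.21e-27). Their median log2 difference was 1.93, or 1.86 with values below the background bound set to the bound. Ifit1, an interferon-induced inhibitor of translation, rose 40.4-fold (log2 difference 5.34 ± 0.174, SE, limma adjusted p = 2.41e-11), and Iigp1, an interferon-inducible GTPase, rose at least 22.6-fold. Usp18, which removes the ubiquitin-like ISG15 from proteins, rose 7.98-fold. Mean spike-in signal was lower with AML1/ETO than with GFP, as given above, although the arrays overlapped (8.63 on AML1/ETO replicate 2 against 8.39 on GFP replicate 2) and no spike-in probe set passed. The call held with an estimated correlation (adjusted p = 0.00521).

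Genes of cell division fell with AML1/ETO. All 29 measured genes of the G2 and M phase list fell, also adjusted over the list alone (camera adjusted p = 4.11e-15, and adjusted p = 0.00821 with an estimated correlation). Aurkb, a mitotic kinase, was 3.23-fold lower and Tacc3, a spindle protein, 2.86-fold lower. Of 28 S phase and DNA replication genes 25 fell, 0 rose and 3 did not pass, and 27 fell adjusted over the list alone (camera adjusted p = 3.09e-14, but adjusted p = 0.107 with an estimated correlation). Tk1, thymidine kinase, was 2.76-fold lower and Prim1, a primase subunit, 2.74-fold lower. In the DNA repair list 19 of 27 genes fell, 0 rose and 8 did not pass, and 21 fell adjusted over the list alone (camera adjusted p = 3.28e-08, and adjusted p = 0.00546 with an estimated correlation). Msh6, a mismatch repair protein, fell 4.27-fold and Xrcc6, the Ku70 subunit of end joining, fell 3.12-fold.

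Stem and multipotent progenitor genes shifted upwards with AML1/ETO. Of 21 measured, 11 rose, 4 fell and 6 did not pass, and the counts were the same adjusted over the list alone (camera adjusted p = 0.00127, adjusted p = 0.135 with an estimated correlation). Procr, the endothelial protein C receptor, rose 22.0-fold and Hlf, a transcription factor of stem cells, 19.6-fold, whereas Angpt1, a ligand of the Tek receptor, fell at least 3.08-fold with 1 of 3 AML1/ETO arrays above the bound, and Flt3, a receptor of multipotent progenitors, fell 1.95-fold. Kit, one of the sorted markers, had array signals at or below the background bound in all groups, so that no fold is given for it, and Ly6a, the gene of Sca1, was not analysed here. In the immediate early list 11 of 25 genes rose, 3 fell and 11 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00225, adjusted p = 0.135 with an estimated correlation). Fos rose 13.2-fold and Fosl2 at least 6.70-fold, while Myc fell 2.34-fold. The immediate early median log2 difference was 0.233, and 0 with values below the bound set to the bound. For the stem list these medians were 0.517 and 0.177.

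Marker lists of other cell types moved unevenly. A change in the mix of sorted cells cannot be told apart here from a change within cells. Among 20 megakaryocyte and platelet genes 4 rose, 10 fell and 6 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0233, adjusted p = 0.284 with an estimated correlation). Selp, the platelet adhesion receptor P-selectin, fell 10.3-fold and Nfe2, a transcription factor of platelet formation, 8.06-fold. The platelet chemokine genes Ppbp and Pf4 rose 4.73-fold and 3.64-fold. The call ended when the 40% of genes with the lowest mean were dropped (adjusted p = 0.0719) and, in a choice made after seeing the data, with the Gapdh difference as a covariate (adjusted p = 0.0536) or among genes above the bound in a group (0.126). Of 20 stromal and endothelial genes 7 rose, 2 fell and 11 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0233, adjusted p = 0.128 with an estimated correlation). That call was lost without the 40% dimmest genes (adjusted p = 0.147), with the spike-in (0.0506) or Gapdh (0.0503) covariate, and among genes above the bound in a group (0.289). Col1a2, a fibrillar collagen chain, was at least 8.15-fold higher and Sparc, a matrix protein, at least 5.86-fold higher, while Pdgfrb was at least 3.76-fold lower. Of 23 Wnt genes 7 rose, 2 fell and 14 did not pass, and 8 rose and 2 fell adjusted over the list alone. Fzd4, a Wnt receptor, rose at least 3.04-fold and Ccnd1, cyclin D1, fell 3.77-fold. The Wnt call (camera adjusted p = 0.0406) was lost with an estimated correlation (adjusted p = 0.135), without the 40% dimmest genes (0.118), with the spike-in (0.0892) or Gapdh (0.0606) covariate, among genes above the bound in a group (0.384), and without GFP replicate 1 (0.0686).

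The remaining cell-type lists did not pass in this comparison. In the mast cell, basophil and eosinophil list 4 of 19 genes rose and 4 fell (camera adjusted p = 0.815). The basophil and mast cell genes Cd200r3 and Hdc rose at least 17.9-fold (Cd200r3 above the bound on 1 of 3 GFP arrays) and 16.6-fold. The eosinophil granule genes Epx and Prg3 fell 13.6-fold and 7.99-fold. In the neutrophil and granule list 4 of 23 rose and 9 fell, or 4 and 12 adjusted over the list alone (camera adjusted p = 0.379). Lcn2 rose 8.46-fold, whereas the granule gene Ngp fell 8.70-fold on average. Ngp had a value of 5.88 on AML1/ETO replicate 3 against 3.15 and 2.60 on the other AML1/ETO arrays. Chil3 was 9.86 on replicate 3 against 7.61 and 7.15. The mean over the neutrophil and granule list was 4.69 on that array against 4.21 and 4.18. GFP arrays had list means of 4.46 to 4.76. Of 27 monocyte, macrophage and dendritic cell genes 6 rose and 10 fell, or 7 and 10 adjusted over the list alone (camera adjusted p = 0.761). Cd14 was up 7.07-fold, Adgre1 up 5.47-fold, Lgals3 down 2.67-fold and H2-Ab1 down 2.08-fold. Of 21 erythroid genes 3 rose and 5 fell (camera adjusted p = 0.594). Car2, a carbonic anhydrase, was 2.43-fold higher while Hemgn and Aqp1 fell as above. Of 19 B lymphoid genes 2 rose and 3 fell (camera adjusted p = 0.479), with Dntt, the terminal transferase, up 4.42-fold and Ighm down 4.35-fold. Of 18 T and NK lymphoid genes 1 rose and 3 fell (camera adjusted p = 0.407), among them Thy1, down 4.29-fold. The 1 that rose, Gata3, lay below the background bound on every array. A group mean exceeded the bound for 8 erythroid, 7 B lymphoid and 4 T and NK lymphoid genes. The remaining members of these lists lay at background in both groups and cannot show whether they changed. For the erythroid list the median log2 difference was positive (0.06) while mean and test pointed down, and for the mast cell, basophil and eosinophil list the median was negative (-0.03) while mean and test pointed up.

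Both partners of the fusion have a mouse gene on the array. Runx1, the gene of AML1, was 1.90-fold higher with AML1/ETO (log2 difference 0.93 ± 0.132, SE, limma adjusted p = 6.46e-05). Runx1t1, the gene of ETO, was at least 1.68-fold higher with AML1/ETO (limma adjusted p = 5.48e-06), while all GFP and W692A arrays lay below the background bound. The positions of these probe sets on the transcripts were not used here, so that neither value can be assigned to the construct or to the cell's own gene. The list of reported AML1/ETO and RUNX1 targets, taken from background knowledge, had 7 members that rose and 7 that fell among 29, or 9 and 8 adjusted over the list alone (camera adjusted p = 0.551). In it Cebpa, a transcription factor of granulocyte development, fell 8.04-fold and Bcl2, an inhibitor of apoptosis, 3.93-fold.

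**Figure D1:**
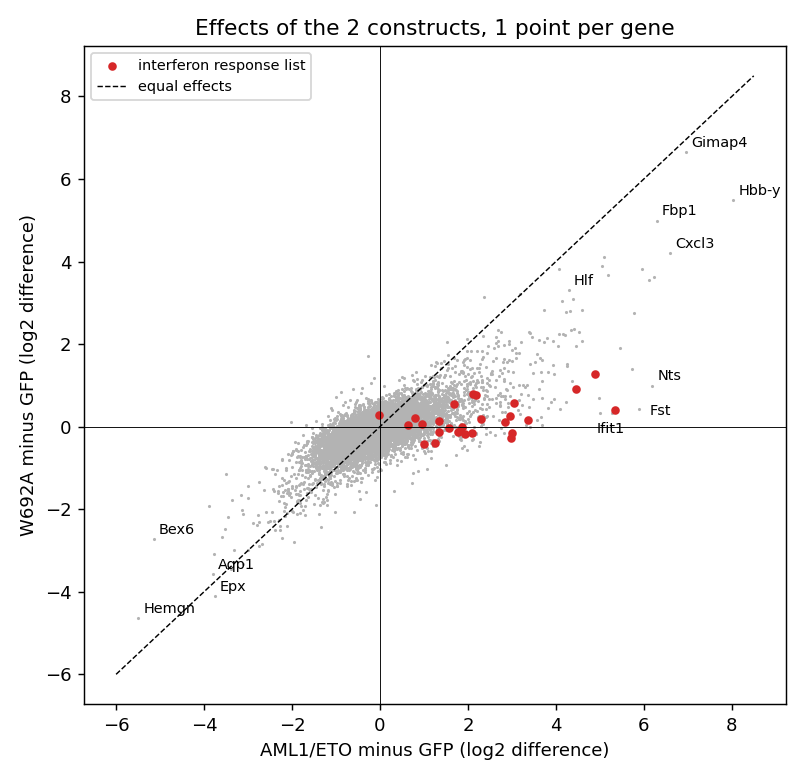
Each grey point is a gene, with its AML1/ETO minus GFP log2 difference on the horizontal axis and its W692A minus GFP log2 difference on the vertical axis; red points are the interferon response list and the dashed line marks equal effects. Gimap4 lies near the dashed line (6.95 and 6.66), Fst lies near the horizontal axis (5.89 and 0.42), and the interferon genes spread to the right with a median of 1.93 against 0.12.

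The second comparison asks what the substituted fusion changed against the empty vector. Gimap4 rose at least 55.9-fold with W692A, Fbp1 at least 22.8-fold, Cd200r4, of the CD200 receptor family, at least 15.2-fold (above the bound on 2 of 3 GFP arrays), Hbb-y at least 15.2-fold and Ctla2b 14.8-fold. Vegfc rose 14.2-fold, Hmga2, a chromatin protein of fetal stem cells, 14.1-fold, Cd59a, a complement inhibitor, 12.9-fold, Cxcl2 12.3-fold and Cxcl3 at least 11.8-fold. The largest falls by log2 difference were in Hemgn (25.0-fold), Epx (17.3-fold), Tesc (8.43-fold), Prg3 (7.91-fold), Il1r1, the interleukin-1 receptor (7.43-fold), Tuba8, an alpha tubulin (at least 6.64-fold, above the bound on 2 of 4 W692A arrays), Khdc1a (at least 6.15-fold), Aqp1 (at least 5.93-fold), Pdgfrb (at least 3.76-fold) and Diras2 (at least 3.66-fold). Gimap4 differed by 6.66 ± 0.202 on the log2 scale (SE, 4 arrays against 3, limma adjusted p = 2.14e-11) and Hemgn by -4.64 ± 0.189 (limma adjusted p = 6.87e-10). Runx1 was 2.11-fold higher (limma adjusted p = 3.04e-05).

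With W692A, 2642 genes passed the limma threshold against GFP, 991 higher and 1651 lower, and 1637 of them differed by at least 1.5-fold. After a further quantile normalization the split was 1262 higher and 1352 lower. The Gapdh 3′ minus 5′ difference separated every W692A array from every GFP array, and with it as a covariate, a choice made after seeing the data, 506 genes passed. In that fit the median standard error of the 2642 genes was 1.73 times as large, their median absolute log2 difference went from 0.656 to 0.577, and 99.0% kept their sign.

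Interferon response genes did not pass as a list with W692A: 5 of 27 rose, 1 fell and 21 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0972), and their median log2 difference was 0.12. Without W692A replicate 3 the list passed (adjusted p = 0.0432), and over all alternatives that used camera the adjusted p ran from 0.0432 to 0.453. With fry, which does not compare a list with other genes, the adjusted p was 0.0433. Ifit1 differed by 0.41 (limma adjusted p = 0.121). Cell division lists did not pass either. Of 29 G2 and M phase genes 0 rose and 5 fell, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.358), and of 28 S phase and DNA replication genes 1 rose and 2 fell (camera adjusted p = 0.187). In the DNA repair list 8 of 27 fell, 0 rose and 19 did not pass, with 10 falling adjusted over the list alone (camera adjusted p = 0.00127, adjusted p = 0.0488 with an estimated correlation), and the call ended with the Gapdh difference as a covariate (adjusted p = 0.0657). Xrcc6 fell 2.06-fold.

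Among stem and multipotent progenitor genes 9 of 21 rose, 4 fell and 8 did not pass with W692A, or 10 and 7 adjusted over the list alone. Hlf rose 9.85-fold and Tek, the angiopoietin receptor, at least 2.72-fold, while Angpt1 fell at least 3.34-fold, with 1 of 4 W692A arrays above the bound. This call (camera adjusted p = 0.0478) was lost with an estimated correlation (adjusted p = 0.284), without the 40% dimmest genes (adjusted p = 0.0541) and with 5 of the 10 arrays left out singly: GFP replicate 3 (adjusted p = 0.137), AML1/ETO replicate 3 (0.0516) and W692A replicates 1 (0.062), 2 (0.0529) and 3 (0.053). It was also lost with the spike-in covariate (0.0735), with the Gapdh covariate (0.0707) and among genes above the bound in a group (0.0674). In the immediate early list 9 of 25 rose, 3 fell and 13 did not pass, or 9 and 4 adjusted over the list alone, with Fos up 7.12-fold and Egr1, a zinc finger factor, up 2.38-fold. Its call (camera adjusted p = 0.0386) was lost with an estimated correlation (adjusted p = 0.225), without the 40% dimmest genes (adjusted p = 0.0541), with the Gapdh covariate (adjusted p = 0.42) and without GFP replicate 1 (adjusted p = 0.0558), W692A replicate 1 (0.062) or W692A replicate 3 (0.0606). The immediate early median log2 difference was 0.139, and 0 with values below the bound set to the bound. For the stem list these medians were 0.368 and 0.198.

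Megakaryocyte and platelet genes fell more often than they rose with W692A, 10 against 2 of 20, with 8 not passing, or 11 against 4 adjusted over the list alone (camera adjusted p = 0.00127, adjusted p = 0.174 with an estimated correlation). Rab27b, a GTPase of platelet granules, fell 3.78-fold and Selp 3.40-fold. Of 21 erythroid genes 0 rose, 5 fell and 16 did not pass, with 6 falling adjusted over the list alone (camera adjusted p = 0.0414, adjusted p = 0.174 with an estimated correlation), and the call ended without GFP replicate 3 (adjusted p = 0.0776), without W692A replicate 2 (0.0675), with the spike-in level as a covariate (0.0506) and with the Gapdh covariate (0.131). The erythroid median log2 difference was -0.00193, and 0.0129 with array medians subtracted, against a mean of -0.546. A group mean exceeded the bound for 8 of the 21 erythroid genes. Of 77 genes of oxidative phosphorylation 16 rose, 2 fell and 59 did not pass, or 20 and 2 adjusted over the list alone, with a median log2 difference of 0.17 (camera adjusted p = 0.000132, adjusted p = 0.174 with an estimated correlation, adjusted p = 0.157 with the Gapdh covariate). Ndufs4, a complex I subunit, rose 1.76-fold, a call that ended without GFP replicate 2 (limma adjusted p = 0.0702).

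The other cell-type lists did not pass for W692A against GFP. In the mast cell, basophil and eosinophil list 3 of 19 rose and 6 fell (camera adjusted p = 0.288), with Cd200r3 up at least 4.49-fold (1 of 3 GFP arrays above the bound) and Epx and Prg3 down as above. In the neutrophil and granule list 5 of 23 rose and 8 fell (camera adjusted p = 0.226), with Mmp8 at least 2.33-fold higher and Chil3 5.43-fold lower. The monocyte, macrophage and dendritic cell list had 5 of 27 rising and 3 falling, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.407), and Adgre1 rose 3.86-fold. Of 19 B lymphoid genes 1 rose and 4 fell (camera adjusted p = 0.0757, and 0.000683 with the Gapdh covariate), Ighm by 4.24-fold downwards. Of 18 T and NK lymphoid genes 1 rose and 4 fell (camera adjusted p = 0.761), and of 20 stromal and endothelial genes 3 rose and 3 fell (camera adjusted p = 0.594), where Sparc was at least 1.38-fold higher and Igfbp7 at least 2.81-fold lower, with 1 of 4 W692A arrays above the bound. In these last 2 lists the median log2 difference was positive (0.08 in each) and the mean negative (-0.08 in each). A group mean exceeded the bound for 7 B lymphoid, 4 T and NK lymphoid and 3 stromal and endothelial genes.

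**Figure D2:**
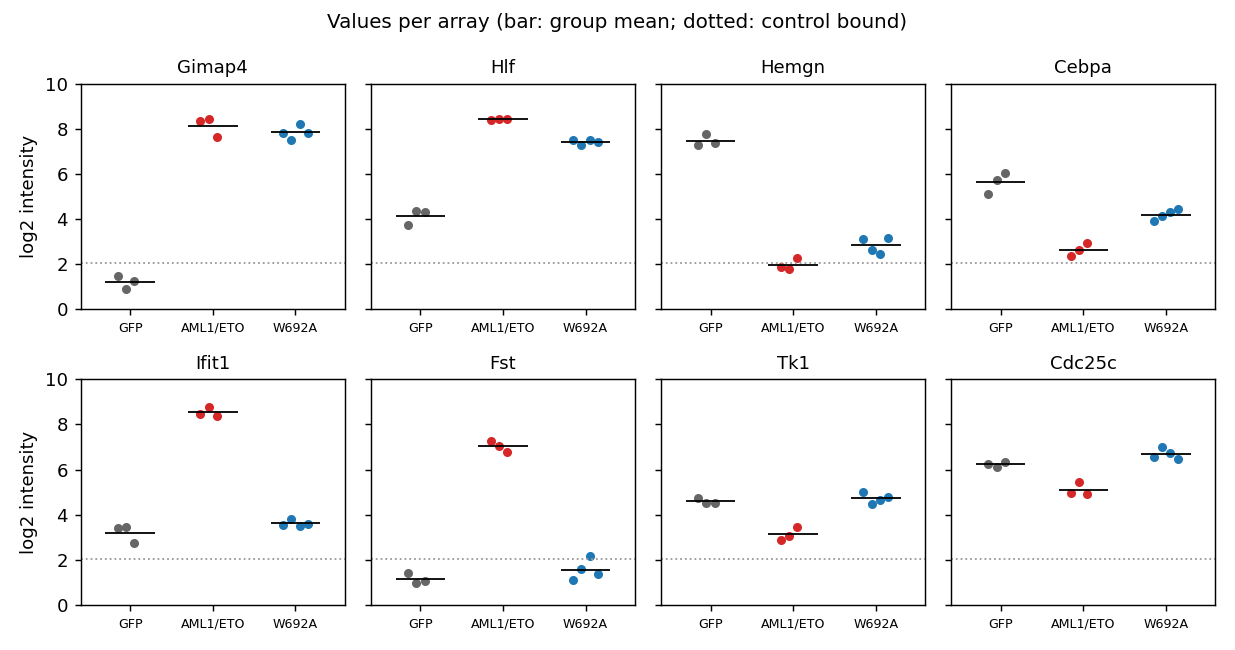
Points are single arrays, the vertical axis is log2 intensity, bars are group means and the dotted line is the background bound of 2.04. Gimap4, Hlf and Hemgn lie apart from GFP with both constructs, whereas for Ifit1 and Fst every AML1/ETO array lies above every array of the other groups; Cebpa, Tk1 and Cdc25c have their lowest group mean with AML1/ETO.

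The third comparison sets W692A directly against AML1/ETO, constructs that by their labels differ in the substitution; virus preparation and construct level were not separated from it. Fst was at least 31.1-fold lower with W692A, Ifit1 30.5-fold, Cxcl5, a neutrophil-attracting chemokine, at least 15.5-fold, Nts at least 22.8-fold, Sprr2d, a cornified envelope protein, 20.2-fold and Ifi27l2a, an interferon-induced gene, 19.3-fold. Sox17, an endothelial and fetal stem cell transcription factor, was at least 11.4-fold lower, Slfn4 at least 8.51-fold, Oxtr, the oxytocin receptor, at least 8.16-fold and Fermt2, an integrin adaptor, at least 4.94-fold. Fst and Cxcl5 exceeded the bound on 1 of 4 W692A arrays, and Cp and Il6ra, named next, on 2 of 3 AML1/ETO arrays. Higher with W692A were Cp (at least 4.64-fold), Slc40a1, the iron exporter ferroportin (3.95-fold), Ffar2 (3.86-fold), Bcl3 (3.31-fold), Il6ra, the interleukin-6 receptor (at least 3.16-fold), Lmna, lamin A (3.27-fold), Gja1, a connexin (3.12-fold), Tk1 (3.03-fold), Bex6 (at least 2.91-fold) and Tgfbi (at least 2.27-fold). Fst differed by -5.47 ± 0.210 on the log2 scale (SE, 4 arrays against 3, limma adjusted p = 7.27e-10) and Cp by 2.34 ± 0.279 (limma adjusted p = 2.78e-05). Gimap4, Aqp1 and Epx, which had changed with both constructs, differed by -0.29 ± 0.202, 0.22 ± 0.159 and -0.35 ± 0.275 and did not pass (limma adjusted p = 0.391, 0.409 and 0.466). Aqp1 lay below the background bound on every array of both constructs, so its value cannot tell whether they differ. Runx1 differed by 0.15 ± 0.124 (limma adjusted p = 0.501), although 1 of its other 5 probe sets was lower with W692A past the threshold and the difference of the mean over its probe sets was -0.14.

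Between W692A and AML1/ETO 3765 genes passed, 1748 higher and 2017 lower with W692A, and 2317 of them differed by at least 1.5-fold. The majority turned with the scaling: with each array's median subtracted 2220 were higher and 1682 lower, and after a further quantile normalization 2009 and 1821.

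Interferon response genes were lower with W692A than with AML1/ETO in 26 of 27 cases, with 0 higher and Psmb8 again not passing (camera adjusted p = 8.04e-35, adjusted p = 0.00444 with an estimated correlation), and the counts were the same adjusted over the list alone. Usp18 was 8.91-fold and Iigp1 12.2-fold lower. Cell division genes were higher with W692A. Of 29 G2 and M phase genes 28 were higher and 0 lower, or 29 and 0 adjusted over the list alone (camera adjusted p = 4.26e-21, adjusted p = 0.00546 with an estimated correlation). Cdc25c, a mitotic phosphatase, was 2.98-fold higher and Kif23, a cytokinesis kinesin, 2.55-fold higher. Of 28 S phase and DNA replication genes 25 were higher and 0 lower, or 27 and 0 adjusted over the list alone (camera adjusted p = 7.48e-19, adjusted p = 0.0687 with an estimated correlation). The replication helicase subunit Mcm5 was 2.50-fold higher. DNA repair genes were higher in 13 of 27 cases and lower in 0, or 17 and 0 adjusted over the list alone (camera adjusted p = 6.26e-07, adjusted p = 0.0077 with an estimated correlation). Msh6 was 2.70-fold and Fancd2 2.29-fold higher.

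Stem and multipotent progenitor genes were lower with W692A in 8 of 21 cases and higher in 0, or lower in 10 adjusted over the list alone (camera adjusted p = 0.000212, adjusted p = 0.107 with an estimated correlation), with Procr 5.68-fold lower. Immediate early genes were lower in 6 of 25 cases and higher in 0, also adjusted over the list alone (camera adjusted p = 0.00497, adjusted p = 0.142 with an estimated correlation), Fosl2 by 5.31-fold and Klf6 by 4.32-fold. The immediate early median log2 difference was -0.202, and -0.0401 with values below the bound set to the bound. For the stem list these medians were -0.352 and -0.242. In the heat shock and unfolded protein list 7 of 25 were lower and 3 higher, or 8 and 3 adjusted over the list alone. The inducible heat shock gene Hspa1b was at least 10.5-fold lower (above the bound on 3 of 4 W692A arrays) and the mitochondrial chaperonin gene Hspd1 1.77-fold higher. That call (camera adjusted p = 0.0406) was lost with an estimated correlation (adjusted p = 0.135), without the 40% dimmest genes (adjusted p = 0.172), with the spike-in covariate (0.0606), with the Gapdh covariate (0.0693), among genes above the bound in a group (0.287) and without AML1/ETO replicate 3 (0.0557) or W692A replicate 3 (0.0629). Genes of oxidative phosphorylation were higher in 21 of 77 cases and lower in 3, or 22 and 3 adjusted over the list alone (camera adjusted p = 1.83e-05, adjusted p = 0.142 with an estimated correlation), Atp5g1, an ATP synthase subunit, by 2.12-fold upwards. Of 49 cytosolic ribosomal protein genes 3 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.000992, adjusted p = 0.245 with an estimated correlation), with a median log2 difference of 0.14. In it Rpl14 was higher by 0.59 ± 0.108 on the log2 scale (SE, limma adjusted p = 0.00104).

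Of the cell-type lists, the mast cell, basophil and eosinophil list was lower with W692A in 7 of 19 cases and higher in 0, also adjusted over the list alone, with Hdc 4.31-fold and Cd200r3 3.98-fold lower. Its call (camera adjusted p = 0.00445) was lost with an estimated correlation (adjusted p = 0.43), with the Gapdh covariate (adjusted p = 0.0649) and without AML1/ETO replicate 3 (adjusted p = 0.07). Stromal and endothelial genes were lower in 6 of 20 cases and higher in 0, also adjusted over the list alone (camera adjusted p = 0.0037, adjusted p = 0.0687 with an estimated correlation), with Col1a2 at least 8.15-fold lower. Only 4 of these 20 genes had a group mean above the bound. The list's median log2 difference was -0.108 as deposited and 0 with values below the bound set to the bound. The other lists of cell types did not pass. In the megakaryocyte and platelet list 6 of 20 were higher and 3 lower, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.411). Selp was 3.03-fold higher and Ppbp 6.59-fold lower. In the neutrophil and granule list 4 of 23 were higher and 3 lower, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.741), and in the monocyte, macrophage and dendritic cell list 5 of 27 were higher and 2 lower, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.232). Of 21 erythroid genes 2 were higher and 3 lower (camera adjusted p = 0.448). Of 19 B lymphoid genes 1 was higher and 3 lower (camera adjusted p = 0.477), and of 18 T and NK lymphoid genes 2 were higher and 0 lower (camera adjusted p = 0.358). A group mean exceeded the bound for 6 erythroid, 7 B lymphoid and 4 T and NK lymphoid genes.

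**Figure D3:**
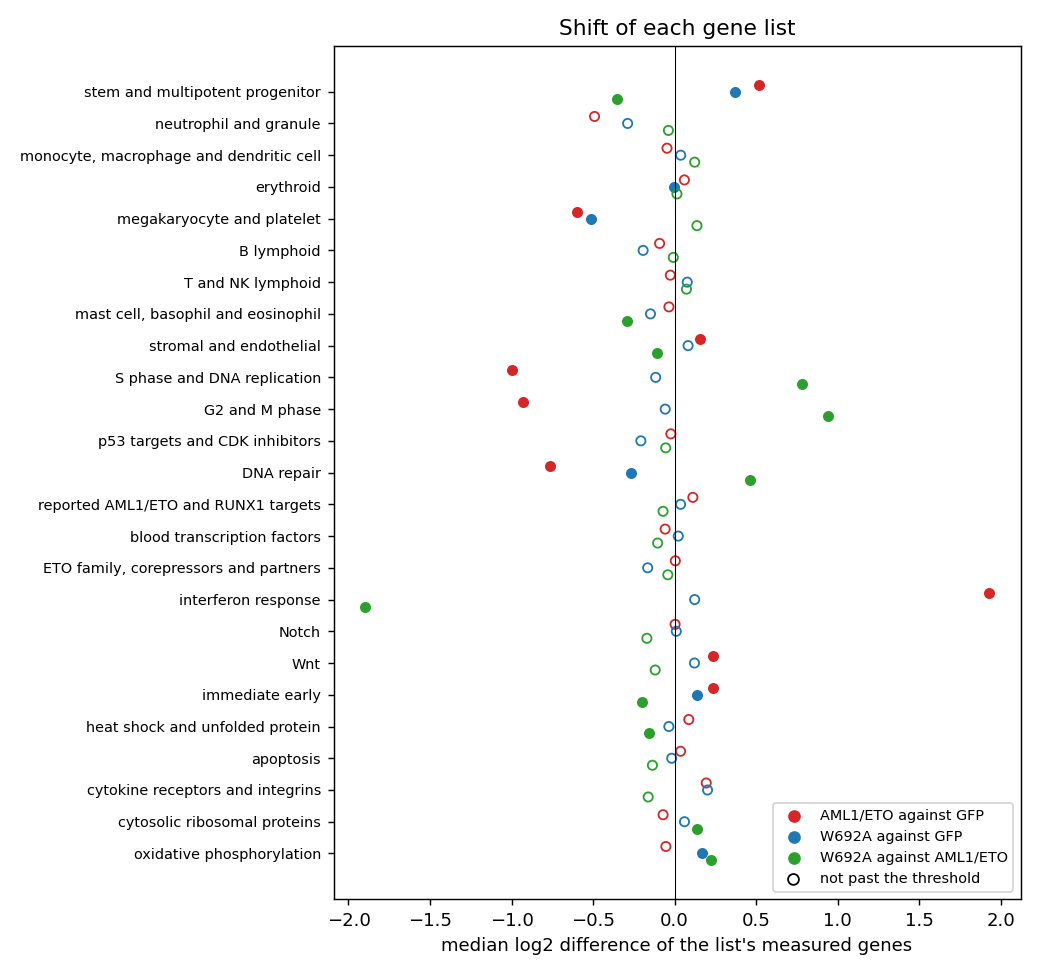
Each point is the median log2 difference of a list's measured genes (horizontal axis) in one of the 3 comparisons; filled points passed the camera test and open points did not. The interferon response list stands at 1.93 for AML1/ETO against GFP, 0.12 for W692A against GFP and -1.90 for W692A against AML1/ETO.

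The effects of both constructs against GFP were then set side by side over all 18193 genes. The slope of the W692A effect on the AML1/ETO effect, with the noise of the estimates and of the shared GFP arrays removed, was 0.445 ± 0.0162 (SE from leaving out each array in turn). The uncorrected correlation across genes, which are not independent replicates, was 0.734, where simulated unchanged groups against the same GFP arrays gave 0.533. The covariance was 0.196 against a simulated 0.0135, a difference of 0.183. Of the called genes 753 were higher with both constructs and 1231 lower with both, where independent lists of the same sizes would share 127 and 260. Those 3 GFP arrays cannot be split so that each part keeps 2, so that part of the excess may come from the shared controls. The numbers for independent lists also treat all 18193 genes as equally likely to pass. Only 8820 had a group mean above the bound, so dim genes that seldom pass may add to the excess. W692A differed from AML1/ETO in the direction of GFP for 2933 of the 5207 genes changed by AML1/ETO (56.3%) and in the direction away from GFP for 35 (0.672%). Among the 2933 were 43 genes called against GFP in opposite directions with the 2 constructs. Of the 2642 genes called with W692A, 615 (23.3%) did not pass with AML1/ETO, and 242 of these also differed between W692A and AML1/ETO. In simulated data in which W692A had the effect of AML1/ETO, 0.15 genes on average differed from AML1/ETO in the direction of GFP.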

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

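Chosen only after the result was seen were the test of RNA integrity on the interferon genes and both tests on Runx1t1; the spike-in covariate and the restriction to genes above the bound were added after seeing the data.

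Interferon response genes were higher with AML1/ETO than with GFP, by a median log2 difference of 1.93, and their median with W692A was 0.12. With the spike-in level as a covariate the AML1/ETO median was 1.98, between 1.92 and 2.05 with each array left out, which argues against the amount of labelled target as the whole cause. The W692A median was 0.0639 of the AML1/ETO one (0.0284 to 0.0641 with each array left out), although the Gapdh shift of W692A was 1.67 times that of AML1/ETO (1.04 to 2.49), which argues against RNA integrity. Virus preparation cannot be told apart from the encoded protein, since the labels name no second preparation of a construct, and the W692A median of 0.123 came from its own virus. The substitution itself may account for the difference and stays open as a hypothesis.

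Across genes the W692A effects followed the AML1/ETO effects with a slope of 0.445 and to a different extent per gene, although 615 of 2642 W692A calls did not pass with AML1/ETO and 43 went in opposite directions. One common scaling of every effect would bring the noise-corrected correlation across genes to 0.95 or more, and it was 0.763 (0.743 to 0.777 with each array left out). Among genes above the bound on all arrays it was 0.755 (0.739 to 0.771), which argues against the floor of the scale, and with the spike-in covariate 0.783 (0.772 to 0.793), which argues against labelled target. Responses that differ per gene at a lower construct level, other technical differences between the groups and the substitution may each contribute and were not separated.

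Of 6 Runx1t1 probe sets, 3 rose with AML1/ETO, by a mean log2 difference of 1.91, and their mean W692A minus GFP difference was 0.24, a fraction of 0.125. That fraction does not settle whether both constructs were read at like levels, because the AML1/ETO mean of 2.37 lay near the background bound of 2.04. These 3 probe sets were lower with W692A than with AML1/ETO, by log2 differences of -2.154, -1.695 and -1.174. Their limma p-values, adjusted over all probe sets, were 1.28e-05, 0.00177 and 0.00031, and the other 3 did not pass. At the brightest, every AML1/ETO array exceeded the bound and every W692A array lay below it. Runx1 differed between W692A and AML1/ETO by 0.149 at its brightest probe set and by -0.557 (limma adjusted p = 0.00695) to 0.157 at its other 5, and since the probe positions were not used here, a lower amount of W692A construct RNA cannot be told apart from a response of the cell's own gene. A lower construct level could also contribute to the smaller W692A effects.

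For W692A against GFP, only the real split among 35 of the 7 arrays gave its number of genes (2463 in a fit of these groups, highest other 1). The same held for W692A against AML1/ETO (1 of 35, 3665 genes, highest other 0). A share of 1 in 35 is the smallest that these splits can give, so it argues against chance without excluding it. For AML1/ETO against GFP only the real split among 10 did so, with 5255 genes and 0 in the highest other, and 10 splits are too few for a share under 0.05.

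In the group of 4 W692A arrays 1 array stood apart from the rest for 6 of 204 genes and lists tested, where chance gives 10.2; each ratio below is that array's gap over the group's range. Cox7a1 was 2.00 on replicate 3 against 1.67 to 1.70 (ratio 0.905), and Lmna 6.88 on replicate 3 against 6.49 to 6.54 (0.891). Vegfc was 6.51 on replicate 3 against 6.78 to 6.83 (0.858), and Fancd2 3.60 on replicate 4 against 3.50 to 3.51 (0.859). Xbp1 was 10.83 on replicate 4 against 10.61 to 10.64 (0.835), and Runx1t1 0.86 on replicate 1 against 0.53 to 0.59 (0.833).

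The 64 control probe sets, which gave the background bound and the covariates, were not among the genes and lists tested. With limma 1 of them was higher (Gapdh 3′) and 1 lower (transferrin receptor 3′) with AML1/ETO than with GFP, with 23 at an unadjusted p under 0.05. With W692A 5 were higher and 0 lower, with 10 at an unadjusted p under 0.05. Those 5 were the 18S ribosomal RNA probe sets (log2 differences of 0.65 to 0.90, limma adjusted p = 0.0123), the 5′ Gapdh probe set (1.06) and a bacterial phe probe set (0.34). Of 9160 probe sets with no listed gene, 323 were higher and 261 lower with AML1/ETO, and 79 were higher and 163 lower with W692A. Both kinds of probe set were fitted and adjusted apart from the genes. Those counted as higher or lower passed the threshold and also had groups that did not overlap, so the counts are not comparable with those of genes.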

How the results depend on the processing

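The fits with spike-in and Gapdh covariates and the fit of genes above the bound were chosen after seeing the data. The slope kept its sign in the alternatives run for it. Named genes were run singly only with the mean of probe sets, the replicate block, further quantile normalization and each array left out. There the named genes that had passed kept their sign. Differences that had not passed did turn, as for Runx1 between W692A and AML1/ETO (0.1487, and -0.1436 as the mean of probe sets) and for Runx1t1 (-0.01591, and 0.1746 without GFP replicate 1) and Kit (-0.05637, and 0.03505 as the mean of probe sets) between W692A and GFP. Most genes called for W692A against AML1/ETO were lower (2017 against 1748) as deposited and higher with array medians subtracted (2220 against 1682) or further quantile normalization (2009 against 1821). The mean array median of W692A differed from that of AML1/ETO by -0.0684, so subtraction raised every difference by this amount. For the quantile normalization the cause was not tested. With every probe set tested (45101 less 64 controls), 8621, 4006 and 6023 passed for AML1/ETO against GFP, W692A against GFP and W692A against AML1/ETO. These came from more features than the 18193 genes, so the counts are not comparable with those of genes. A 1.5-fold minimum left 1637 genes for W692A against GFP and 2317 for W692A against AML1/ETO, by its construction. The Gapdh covariate left 506 genes for W692A against GFP, 457 of them among the 2642 with the same sign, where standard errors grew. The slope was 0.4631 with the spike-in covariate and 0.3927 with the Gapdh covariate, and the cause was not tested. With an estimated correlation 7 of 26 list calls held, and fry, which does not compare a list with other genes, called 47. Leaving out each array in turn gave 4477 to 5319, 1774 to 2615 and 2943 to 3777 genes, slopes of 0.4365 to 0.4559 and 23 to 27 lists. Counted over named genes, their comparisons and the array left out, the outcome stayed the same in 2764 cases and a call was lost in 136. The 2764 include genes that had not passed in the main fit. The replicate numbers were not taken to pair the arrays, since not every same-numbered pair correlated above 0.1: the pairs ran from -0.13 to 0.46, replicate 1 from 0.26 to 0.46, and 5 of 9 arrays correlated best with their own number. With the replicate block 5272, 2344 and 3509 genes and 27 lists passed, and the slope was 0.4453. Signals near the background bound of 2.04 limit what dim genes show.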

Other observations

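Chosen after seeing the data were the tests with the spike-in or Gapdh covariate and those among genes above the bound.

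Lists of regulators and surface receptors moved in both directions, and none of them passed as a list with AML1/ETO. Of 34 blood transcription factors 13 rose and 9 fell with AML1/ETO, or 13 and 11 adjusted over the list alone (camera adjusted p = 0.594). Id3, an inhibitor of helix-loop-helix factors, rose at least 5.50-fold and Gfi1, a repressor of stem and granulocyte cells, 5.30-fold, while Nfe2 and Cebpa fell 8.06-fold and 8.04-fold. With W692A 11 rose and 5 fell, or 11 and 10 adjusted over the list alone (camera adjusted p = 0.539), and against AML1/ETO 8 were higher and 8 lower, or 9 and 8 adjusted over the list alone (camera adjusted p = 0.954), with Gfi1 4.53-fold lower. Of 30 cytokine receptors and integrins 13 rose and 9 fell with AML1/ETO (camera adjusted p = 0.259), Csf2rb2 by 4.13-fold upwards and Itgb2, the beta chain of leukocyte integrins, by 6.19-fold downwards. With W692A 9 rose and 8 fell, or 12 and 8 adjusted over the list alone (camera adjusted p = 0.226), and against AML1/ETO 7 were higher and 11 lower, or 8 and 11 adjusted over the list alone (camera adjusted p = 0.448). In the ETO family and corepressor list 4 of 21 rose and 6 fell with AML1/ETO, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.741), among them Cbfa2t3, an ETO homologue, down 6.01-fold. With W692A 0 rose and 4 fell, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.0545). That list passed with the replicate block (adjusted p = 0.0422), with the spike-in covariate (0.0304) and without GFP replicate 3 (0.00913) or W692A replicates 1 (0.028) and 4 (0.0384), in a range of 0.00913 to 0.409 over all alternatives that used camera. With fry its adjusted p was 0.0423. Against AML1/ETO 2 were higher and 6 lower (camera adjusted p = 0.496), with Cbfa2t3 2.99-fold higher.

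Lists of growth control and signalling gave counts as follows. Of 28 p53 targets and CDK inhibitors 8 rose and 8 fell with AML1/ETO, or 9 and 8 adjusted over the list alone (camera adjusted p = 0.98), with Sesn1, a stress-induced sestrin, up 2.87-fold. With W692A 3 rose and 8 fell, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.0545). The p53 list passed without GFP replicate 3 (adjusted p = 0.0328), without W692A replicates 1 (0.0411) and 3 (0.0359), and with the Gapdh covariate (0.0144). Alternatives that used camera ran from 0.0144 to 0.338, and fry gave an adjusted p of 0.00271. Against AML1/ETO 1 was higher and 5 lower, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.137). Of 25 apoptosis genes 6 rose and 4 fell with AML1/ETO (camera adjusted p = 0.594), 2 rose and 6 fell with W692A (camera adjusted p = 0.379), and 1 was higher and 5 lower between them (camera adjusted p = 0.0848); Bcl2 fell 3.93-fold and 4.16-fold with the constructs. Of 19 Notch genes 5 rose and 1 fell with AML1/ETO (camera adjusted p = 0.288), 1 rose and 0 fell with W692A (camera adjusted p = 0.626), and 1 was higher and 2 lower between them (camera adjusted p = 0.232), with the receptor gene Notch1 up 2.48-fold and 2.10-fold. Of 23 Wnt genes 3 rose and 1 fell with W692A (camera adjusted p = 0.224), and 1 was higher and 4 lower against AML1/ETO (camera adjusted p = 0.137). Of 25 heat shock and unfolded protein genes 7 rose and 4 fell with AML1/ETO (camera adjusted p = 0.18), and 2 rose and 3 fell with W692A, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.761). Of 29 reported targets 6 rose and 7 fell with W692A, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.954), and 3 were higher and 5 lower against AML1/ETO, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.496). Of 49 cytosolic ribosomal protein genes 0 rose and 5 fell with AML1/ETO, or 0 and 3 adjusted over the list alone (camera adjusted p = 0.288). With W692A 2 rose and 2 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.0659). The ribosomal list passed without W692A replicate 3 (adjusted p = 0.0488) and among genes above the bound (0.0451). Alternatives that used camera ran from 0.0451 to 0.656, and fry gave an adjusted p of 0.0361. Of 77 genes of oxidative phosphorylation 5 rose and 12 fell with AML1/ETO, or 4 and 10 adjusted over the list alone (camera adjusted p = 0.56).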
